A study of Homo sapiens with 17 samples.

How the data were processed

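Single-cell 3′ gene expression was measured on a droplet platform in 17 libraries of human blood cells. Of these, 14 were made from eosinophils: 4 from healthy donors, 6 from donors with moderate asthma and 4 from donors with severe asthma. The other 3 were made from mononuclear cells of healthy donors. Per the labels' protocols, eosinophils were taken from whole blood with a magnetic depletion kit that leaves the wanted cells untouched, without a density gradient, and red cells were removed. Per the submitters' processing notes, reads were processed with Cell Ranger 7.1.0 against GRCh38. Per the file headers, however, 5 eosinophil libraries (moderate replicates 1 and 3, severe replicates 1, 2 and 3) carried version 6.0.0 and the other 12 libraries version 7.0.1. No healthy library carried 6.0.0, so group and version overlap in part. Whether replicates of a group came from separate donors is not given in the sources used here, so every p-value measures the spread between samples.

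The deposited matrices hold raw UMI counts per gene and barcode. Each eosinophil matrix held exactly 10000 barcodes, and the mononuclear matrices held 8620, 9758 and 20126 barcodes, none of them under 500 UMIs. Why exactly 10000 barcodes were kept is not given in the sources used here. The matrices list 36601 genes. XIST, TSIX and Y-linked genes, 103 in all, left before any test because donor sex is not part of the comparisons. Of the 36498 genes kept, 34513 had a position by gene ID in GENCODE 29, on GRCh38, from which all coordinates were taken. Pairs of libraries within a group were checked for duplicates, and the chi-square per degree of freedom was 26.7 or more in every pair. No matrix was therefore a copy of another in its group. Pairs across groups were not checked.

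Kept cells had at least 200 UMIs, at least 100 genes and under 20% mitochondrial UMIs, and were not called doublets. The doublet caller (Scrublet in scanpy 1.11.5, expected rate 0.06) called under 0.5% of barcodes in 14 of the 17 libraries, with a range of 0 to 4.08%, and so cannot be said to have worked; it removed 95 barcodes from the eosinophil libraries. Eosinophil libraries were clustered together, as were the mononuclear libraries, without integration. Counts were scaled to the median total and logged, 2000 variable genes and 30 principal components were used with 15 exact nearest neighbours, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) ran at resolution 0.5 for eosinophil and 1.0 for mononuclear libraries. This gave 10 clusters of 49308 cells and 29 clusters of 37826 cells.

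A cluster took the name of a cell type from marker sets fixed before the data were examined. Genes were ordered by fold over the other clusters, with 20 CPM added. The top 50 had to hold at least 2 markers of the type and more of them than of any other type. They had to number at least 2 times the markers of other types there. At least 3 of its markers had to reach 20 CPM and lie above the other clusters. A cluster of low depth for its libraries also needed a marker among its top 10, which decided no name. A cluster with 3 or more neutrophil precursor granule genes in its top 10 stayed unnamed, as did clusters with no such markers. This scoring rule was revised several times after clusters had been looked at, and the neighbour search was made exact after a first clustering had been seen; the markers were not changed. Types are written as "eosinophil-like" and so on, since names rest on RNA alone. Genes used to pick cells are not independent evidence on the cells picked.

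Counts were summed over the eosinophil-like cells of each library, since cells are not replicates. A library needed at least 30 such cells. Severe replicate 1 had 24 and left the gene tests, which leaves 13 eosinophil libraries: 4 healthy, 6 moderate and 3 severe. The sums held 881878 to 6508800 UMIs per library, and TMM factors lay between 0.971 and 1.03. For the healthy comparisons, all kept mononuclear cells were summed (31919201 to 71697318 UMIs), and separately the monocyte-like cells alone (954 to 4467 cells, 6190372 to 14486495 UMIs).

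Genes were tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors, filterByExpr, a coefficient per group, R 4.3.3), two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All eosinophil groups shared one fit, with the mean of the moderate and severe coefficients as the asthma effect. The healthy comparisons used the 4 healthy eosinophil and 3 mononuclear libraries only. Values after ± are standard errors for log2 fold changes, taken as the absolute log2 fold change over the square root of F, and SD elsewhere. Moderate and severe asthma were set against the same healthy libraries, so their effects are not independent of each other, and no overlap between them is reported.

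Of the 20 gene lists and 15 marker sets, all fixed before the data were examined, those with at least 3 tested genes were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01, two-sided), adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Fry's directional test asks whether a list's genes move one way on balance and its mixed test whether they change either way, and neither compares a list with other genes. List counts are given over all genes tested and adjusted over the list alone.

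Genes to be named were chosen by a rule fixed before the data were examined. For eosinophil groups, it takes up to 12 genes per direction with the smallest p among those past the threshold with an absolute log2 fold change of at least 1, at least 20 CPM in the higher group and no overlap of library values. Where fewer than 3 genes pass, it takes the 5 per direction with the smallest unadjusted p, given as values. For the cell type comparisons it takes the 12 per direction with the largest absolute log2 fold change among genes past the threshold with at least 100 CPM and no overlap. From each list it takes up to 4 members with the smallest p, and 9 genes of eosinophil identity or steroid response are always named. Immunoglobulin and T cell receptor variable genes, some highly polymorphic HLA and null-allele genes and genes with clone names are never named.

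Where a group had no count of a gene, the fold is given as at least the fold that 3 counts over the group would give. With 1 to 3 counts it is given with a 95% counting interval. Shares of cells in single libraries carry Wilson 95% intervals. These intervals and limits cover counting error only. Shares, cell numbers and depth were compared between groups with exact two-sided permutation tests on the difference in means (scipy 1.17.1), adjusted within each family. Correlations across libraries used 100000 permutations.

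The gene and list tests were first tested on simulated counts with 100 genes changed 2-fold and 100 genes changed 4-fold. EdgeR recovered 36% and 88% of these for moderate asthma against health, 24% and 70% for severe asthma against health, 34% and 92% for severe against moderate asthma, and 51% and 88% for all asthma. For the healthy comparisons it recovered 49% and 94% against mononuclear cells and 30% and 75% against monocyte-like cells. Between 5 and 12 unchanged genes were called in each. Each comparison was also repeated under other splits of the same libraries into groups of the same sizes, all of them or 100 at random.

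Alternatives fixed before the data were examined were DESeq2 1.42.0, edgeR with RLE factors, limma-voom with quality weights, no gene filter, floors of 100 UMIs with 50 genes and 500 UMIs with 200 genes, a mitochondrial limit of 10%, doublets kept, all barcodes summed, only the groups compared, a replicate block, another clustering resolution and leaving out each library in turn. Chosen after seeing the data were the header version as a covariate, libraries of one header version only, severe replicate 1 kept, the eosinophil-like cluster of fewest UMIs left out, ribosomal protein and mitochondrial genes left out before scaling, and the libraries of the blocked fit without the block. The titles' codes pair 3 healthy eosinophil with 3 mononuclear libraries, but the labels do not say that a code marks a donor, so the pairing is an alternative.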

Results

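Gene expression was measured in single cells of 17 droplet libraries from human blood. Eosinophils, granulocytes of type 2 immunity that carry toxic granule proteins and take part in asthma, were collected from healthy donors (4 libraries), donors with moderate asthma (6 libraries) and donors with severe asthma (4 libraries). Mononuclear cells, in principle lymphocytes and monocytes, were collected from healthy donors (3 libraries). Their 37826 kept cells also held clusters named erythroid (1199 and 2299 cells), platelet (1941 and 791), neutrophil (933) and basophil or mast (801). All of these were summed into the mononuclear reference. Some clusters came almost wholly from a single library, as did 99.9% of a T-like cluster of 6533 cells. The deposited raw counts held 6348524 to 16173965 UMIs per healthy eosinophil library, 5439632 to 19322229 per moderate library, 3146259 to 14447698 per severe library and 32079881 to 71846056 per mononuclear library. Eosinophil libraries kept 1055 to 9472 cells each. The labels do not say whether replicates are separate donors, so tests measure the spread between samples.

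The first question was how pure the eosinophil libraries were and whether their make-up differed by disease. Eosinophil-like cells made up a mean of 66.6% ± 14.6 (SD, n = 4) of kept cells in health, 76.7% ± 21.5 (n = 6) in moderate asthma and 67.3% ± 43.4 (n = 4) in severe asthma. None of these mean shares differed beyond the spread between libraries (exact permutation p = 0.486 for moderate against healthy, 0.971 for severe against healthy and 0.724 for severe against moderate, two-sided). Purity by UMIs was another matter. Kept UMIs outside eosinophil-like cells made up 66.4 to 92.5% in healthy and 33.8 to 76.7% in moderate libraries. In the severe libraries other than replicate 1 they made up 37.1 to 76.6%. The group difference in this measure was not tested. Basophil-like or mast-like cells, which also carry type 2 mediators, averaged 3.87% ± 5.31, 0.222% ± 0.141 and 1.73% ± 3.15 in the same order. Plasma-like cells averaged 1.71%, 0.473% and 2.41%, and erythroid-like cells 0.301%, 0.141% and 5.12%. The smallest of the 15 exact permutation p-values was 0.171, for plasma-like cells in severe against moderate asthma (adjusted p = 0.893). Unnamed clusters averaged 27.5%, 22.4% and 23.4% of kept cells. The largest of them, of 6869 cells, held none of the fixed markers among its leading 50 genes. A cluster of 3322 cells was led by KLRB1, GZMB and IL7R but held 3 progenitor markers, and at the higher clustering resolution a cluster of 2545 cells led by KLRB1 was named progenitor. The others were led by neutrophil precursor granule transcripts (DEFA3, LTF, CAMP) and by CST3 and VCAN, with conventional dendritic and classical monocyte markers. Severe replicate 1 had only 24 eosinophil-like cells among 1055, or 2.27% (Wilson 95% interval 1.53 to 3.36), and moderate replicate 3 had 33.9% (33.0 to 34.9). In moderate replicate 3 no barcode had under 266 UMIs, so the floor of 200 UMIs removed none. There 95.3% of barcodes passed the UMI, gene and mitochondrial limits, against 10.6 to 52.6% in the other eosinophil libraries. Whether the floor parts cells from background in that library was not tested, which limits its share and the moderate mean.

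Eosinophil-like cells fell into 3 clusters that differed in depth and in their leading genes. Cluster 0 had a median of 521 UMIs per cell. Cluster 1 had a median of 999 and was led by CLC, the Charcot-Leyden crystal protein, with the protease PRSS33 and the lipoxygenase ALOX15. Cluster 2 had a median of 1307.5 and was led by the granule ribonuclease RNASE2, the chemokines CCL4L2 and CCL4, the interferon-induced RSAD2 and the cytokine-induced kinase PIM1. In health these clusters held 40.8%, 47.0% and 12.2% of 6779 eosinophil-like cells. The shares were 26.9%, 56.5% and 16.5% of 17905 cells in moderate asthma and 37.8%, 22.6% and 39.6% of 9903 cells in severe asthma. These shares pool the cells of a group, and 42.9% of cluster 2 came from a single library. Median UMIs per eosinophil-like cell averaged 684 ± 91.4 in health, 1042 ± 445 in moderate and 1018 ± 307 in severe asthma. The exact permutation p was 0.0571 for severe against healthy (adjusted p = 0.343 over 9 tests of depth and cell number) and 0.190 for moderate against healthy. Among libraries with a 7.0.1 header, the eosinophil-like share averaged 85.4% ± 6.31 in moderate asthma (n = 4) and 66.6% in health, with an exact permutation p of 0.114. That header version held only 1 severe library and version 6.0.0 no healthy one. Within 6.0.0, severe (n = 3) and moderate (n = 2) means were 61.0% and 59.3%, with an exact permutation p of 1.0 where 0.2 was the smallest possible.

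**Figure D1:**
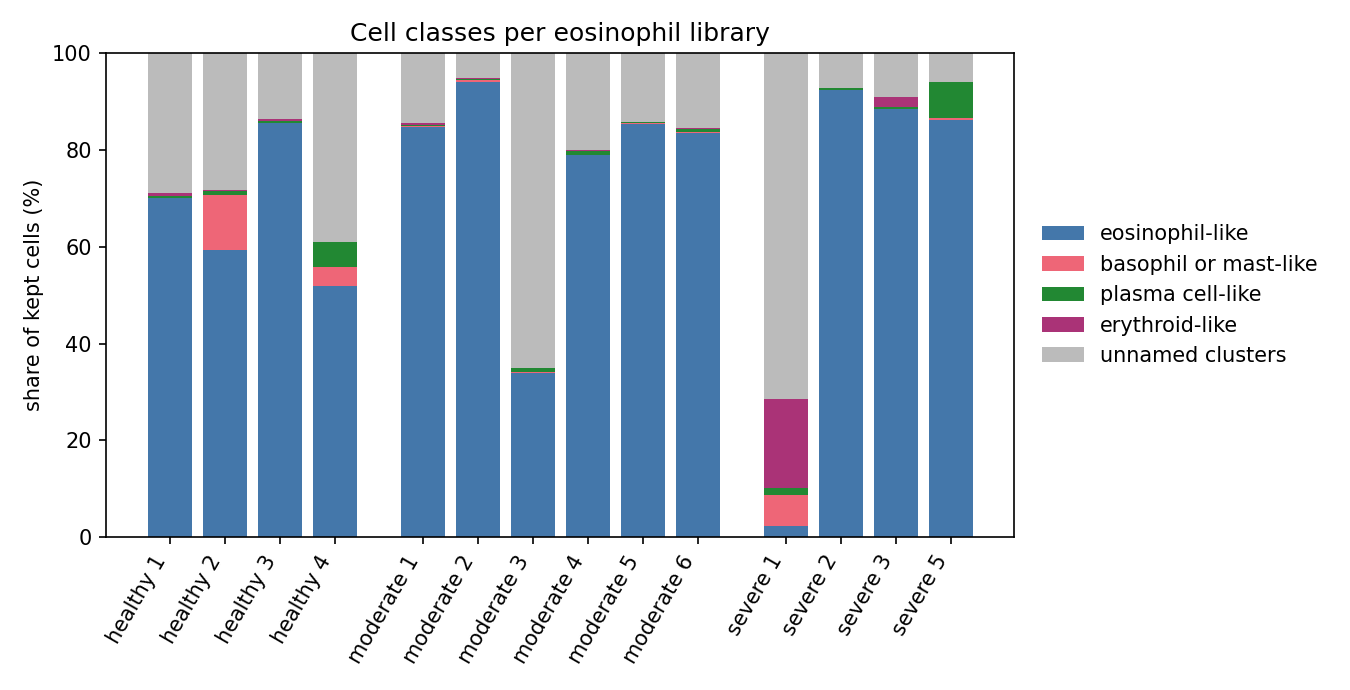
Share of kept cells (percent, vertical axis) in each cell class for the 14 eosinophil libraries, stacked per library and grouped by health, moderate and severe asthma. Severe replicate 1 has 2.27% eosinophil-like cells and moderate replicate 3 has 33.9%.

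Healthy eosinophils set against all healthy mononuclear cells showed which transcripts differed between these preparations. Neutrophils were not compared on their own, so genes shared by granulocytes cannot be told from genes of eosinophils alone. Barcodes were also kept differently in eosinophil and mononuclear matrices, so cell type and preparation cannot be separated. These limits hold for the comparison with monocyte-like cells too. Eosinophil-like cells carried far more of many receptors, granule proteins and lipid enzymes of the lineage. Transcripts of T cells, NK cells, monocytes and platelets and those of ribosomal proteins were far lower. As lists, only eosinophil identity genes and eosinophil markers kept their call with an estimated correlation. Of 11546 genes, 7650 passed the edgeR threshold, 3508 higher and 4142 lower in eosinophil-like cells (n = 4 against 3). Library values did not overlap for 7672 genes, where chance would give 5.71% of genes. The largest increase was PRSS33 (ENSG00000103355, chromosome 16, 2783953 to 2787948), at 13.13 ± 0.62 log2 (490.4 CPM against 0.0592, adjusted p = 4.7e-07). ALOX15 (ENSG00000161905, chromosome 17, 4630902 to 4642294), which makes lipid mediators from arachidonic acid, rose by 10.79 ± 0.32. The inhibitory lectin SIGLEC8 (ENSG00000105366, chromosome 19, 51450847 to 51458456) had 3 counts in mononuclear cells, for a ratio of 6193 (2119 to 30031). The interleukin-5 receptor IL5RA (ENSG00000091181, chromosome 3, 3066326 to 3126613), target of antibodies that deplete eosinophils, rose by 6.58 ± 0.29 (456.4 ± 52.8 against 4.81 ± 1.67 CPM). CLC (ENSG00000105205, chromosome 19, 39731250 to 39738028) rose by 7.50 ± 0.79 to 6574 ± 956 CPM. The eotaxin receptor CCR3 rose by 4.98 ± 0.57, RNASE2 by 5.65 ± 0.67, the IL-33 receptor IL1RL1 by 5.58 ± 0.80 and the steroid-induced TSC22D3 by 1.56 ± 0.37. FKBP5, another steroid-induced gene, was -0.50 ± 0.43 (adjusted p = 0.328). Several of these genes were among the markers that picked the cells, so their rise is not independent evidence.

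In the opposite direction, the T cell receptor chain CD3G (ENSG00000160654, chromosome 11, 118344344 to 118355161) had no count in eosinophil-like cells, a fall of at least 313-fold. The T cell maturation gene THEMIS (ENSG00000172673, chromosome 6, 127708072 to 127918631) had 1 count, for a ratio of 1399 (251 to 55270). The platelet chemokine PPBP (ENSG00000163736, chromosome 4, 73987038 to 73988197) was at -9.71 ± 0.63. By list, all 18 identity genes rose (median 5.14, the same with OLIG2 at its lower limit, camera adjusted p = 3.4e-30) and so did all 13 eosinophil markers (median 5.91). These calls held with an estimated correlation, with adjusted p = 0.0236 and 0.0355. Both lists hold markers that picked the cells, so their calls are not independent evidence. Other calls rested on the preset correlation. Of 5 granule genes 4 rose (median 5.65, adjusted p = 0.0468; adjusted p = 0.253 with an estimated correlation). Of 19 eicosanoid genes 12 rose and 2 fell (median 1.92, adjusted p = 3.5e-05; adjusted p = 0.0862 with an estimated correlation), among them CYSLTR2 (4.95) and ALOX5AP (3.13) of the leukotriene pathway. Chemoattractant receptors and adhesion genes had 16 rises and 3 falls (median 0.996, adjusted p = 0.0037; adjusted p = 0.105 with an estimated correlation), led by ADGRE2, PTAFR and ADGRE5. Receptors for type 2 and alarmin cytokines had 7 rises and 2 falls, with the shared beta chain CSF2RB at 3.12 and IL7R at -5.94 (median 1.53, adjusted p = 0.0354; adjusted p = 0.253 with an estimated correlation). Fc and Siglec receptors had 9 rises and 5 falls (median 0.91, adjusted p = 0.0037; adjusted p = 0.345 with an estimated correlation). Of 78 ribosomal protein genes 76 fell (median -2.89, adjusted p = 3.4e-28; adjusted p = 0.332 with an estimated correlation). All 15 T cell markers fell (median -7.52, or -7.14 with genes without a count at their limit; adjusted p = 0.0883 with an estimated correlation), as did all 10 NK markers (median -5.51), all 12 platelet markers (-7.48), 10 of 11 classical monocyte markers (-3.05) and all 6 nonclassical ones (-3.61). Immediate early genes had a median of 0.42 but a mean of -0.07, and glycolysis and hypoxia genes 0.04 and -0.07, with neither list called. Counts adjusted over the list alone were the same for all lists named here.

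Monocytes are the other myeloid cells of the mononuclear fraction, so eosinophil-like cells were also set against monocyte-like cells alone. The eosinophil program stood out again, while markers of classical and nonclassical monocytes were far lower in eosinophil-like cells. Again, only the identity and eosinophil marker lists kept their call with an estimated correlation. Of 10969 genes, 6043 passed the edgeR threshold, 2831 higher and 3212 lower, and values did not overlap for 6362 genes (chance share 5.71%). PRSS33 and SIGLEC8 had no count in monocyte-like cells, for rises of at least 5754-fold and at least 1490-fold. ALOX15 had 2 counts, for a ratio of 6079 (1683 to 50195). CLC rose by 8.87 ± 1.5, IL5RA by 8.64 ± 0.58, CCR3 (ENSG00000183625, chromosome 3, 46163604 to 46266706) by 6.79 ± 0.77, RNASE2 by 3.92 ± 0.64, IL1RL1 by 6.44 ± 1.0 and TSC22D3 by 1.89 ± 0.36. FKBP5 was at -0.85 ± 0.51 (adjusted p = 0.188). The sphingomyelinase SMPD3 (ENSG00000103056, chromosome 16, 68358325 to 68448688) rose by 8.03 ± 0.32 (498.6 ± 20.8 against 2.0 ± 0.896 CPM), and the macrophage growth factor CSF1 by 7.14 ± 0.57. The lipopolysaccharide co-receptor CD14 (ENSG00000170458, chromosome 5, 140631728 to 140633701) had 1 count in eosinophil-like cells, for a ratio of 1741 (313 to 68773). The matrix proteoglycan VCAN (ENSG00000038427, chromosome 5, 83471465 to 83582303) was at -9.68 ± 0.55 (4.89 against 3809 CPM) and the Toll-like receptor TLR2 at -7.85 ± 0.46.

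By list, all 18 identity genes (median 5.66, adjusted p = 1.5e-30) and all 13 markers (median 8.03) rose, and held with an estimated correlation (adjusted p = 0.0118 and 0.0400). Here too, both lists hold markers that picked the cells. All 4 granule genes rose (median 5.44, adjusted p = 0.0042; adjusted p = 0.201 with an estimated correlation). Eicosanoid genes had 10 rises and 3 falls (median 0.67, adjusted p = 0.0032; adjusted p = 0.151 with an estimated correlation), with ALOX5AP at 3.90 and the leukotriene A4 hydrolase LTA4H at -3.58. Receptors for type 2 and alarmin cytokines had 6 rises and 1 fall (median 1.23, adjusted p = 0.0084; adjusted p = 0.298 with an estimated correlation). Ribosomal protein genes had 76 falls of 78 (median -1.94, adjusted p = 2.2e-18; adjusted p = 0.533 with an estimated correlation). All 11 classical monocyte markers (median -4.82) and all 6 nonclassical markers (-5.26) fell, and neither list was called with an estimated correlation. Markers of plasmacytoid dendritic cells were called higher by camera (median 1.09, adjusted p = 0.0075; adjusted p = 0.298 with an estimated correlation), a list that includes SMPD3, which is also an eosinophil marker. All 11 T cell markers tested (median -5.61) and 8 of 9 platelet markers (-6.38) fell as well, although monocytes should carry little of either. The Fc and Siglec list had a median of -0.21 and a mean of -0.18 although its test pointed up, and was not called. Counts adjusted over the list alone were the same for these lists, and free RNA of other cells was not removed from either side of this comparison.

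**Figure D2:**
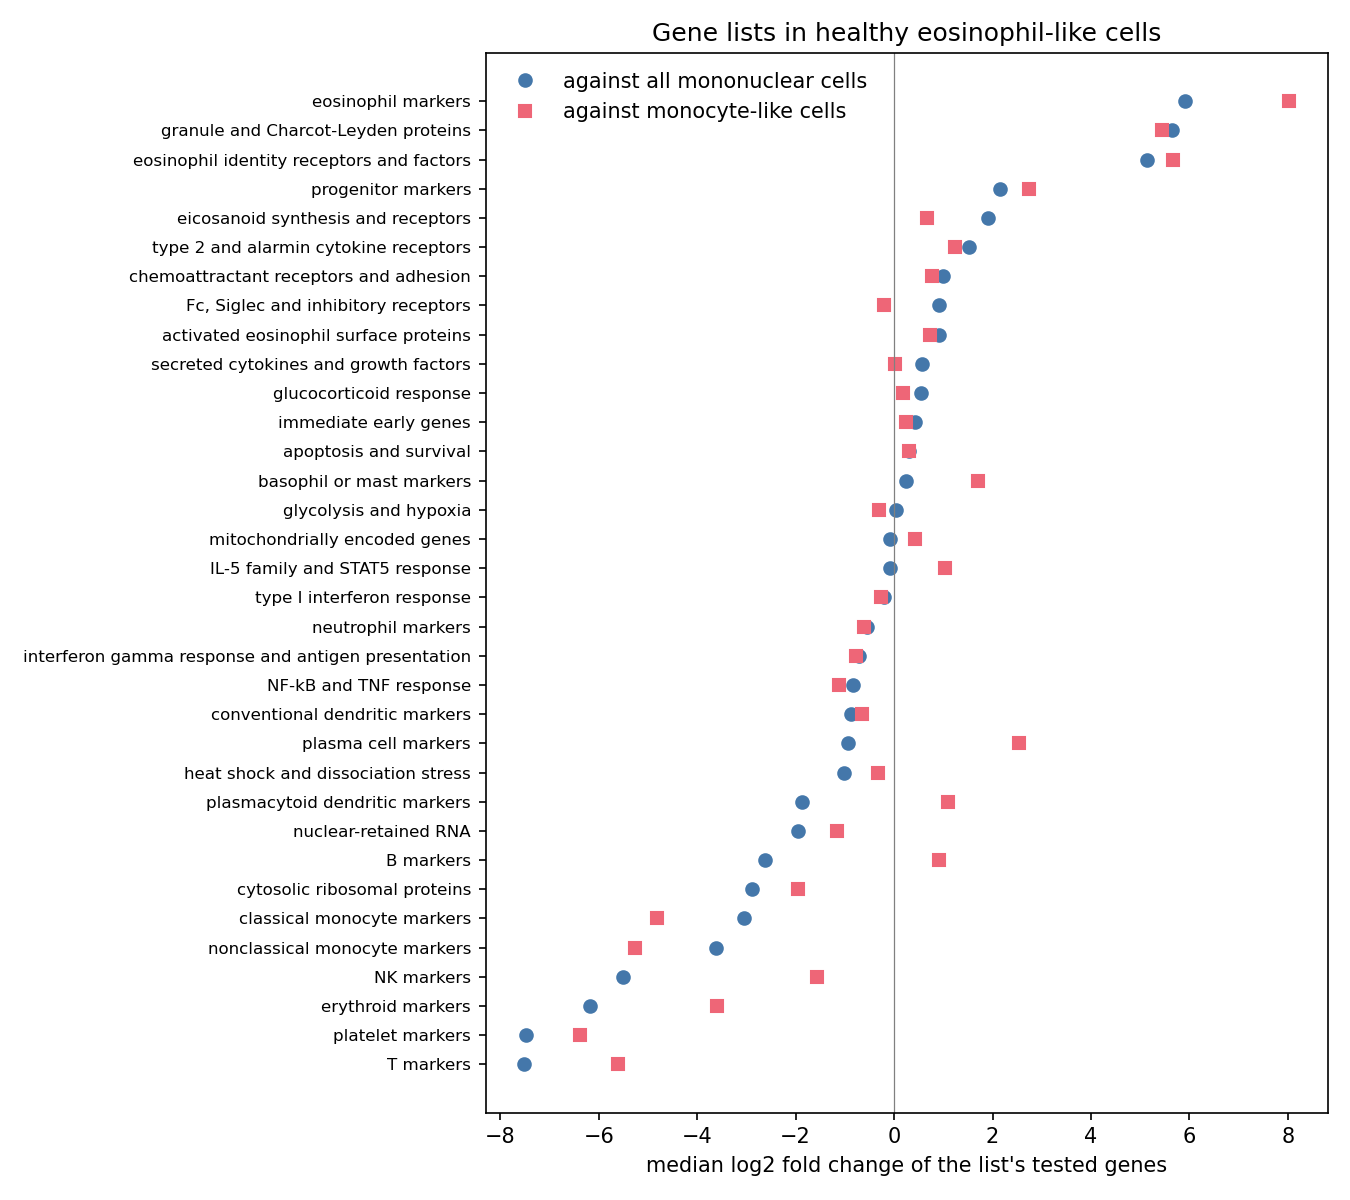
Median log2 fold change of each gene list (horizontal axis) in healthy eosinophil-like cells (n = 4) over all mononuclear cells and over monocyte-like cells (n = 3). Eosinophil identity genes sit at 5.14 and 5.66, and ribosomal protein genes at -2.89 and -1.94.

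Moderate asthma was compared with health to ask whether circulating eosinophils already differ in milder disease. As lists, and with the preset correlation only, identity genes stood slightly higher and basophil and progenitor markers lower in moderate asthma, and no single gene passed. By edgeR 0 of 11381 genes passed (n = 6 against 4), with a lowest adjusted p of 1.0 and 447 genes at unadjusted p under 0.05. DESeq2 and limma-voom also called 0. Library values did not overlap for 122 genes, where chance would give 0.952% of genes. The urokinase receptor PLAUR (ENSG00000011422, chromosome 19, 43646095 to 43670547), which guides adhesion and migration, was at 0.88 ± 0.20 log2 (349.1 ± 89.3 CPM against 189.8 ± 31.1). The adhesion scaffold CASS4 (ENSG00000087589, chromosome 20, 56412112 to 56460387) was at 0.57 ± 0.14, and LGALS12 (ENSG00000133317, chromosome 11, 63506084 to 63516774), a galectin like CLC, at 0.78 ± 0.20 (211.1 ± 43.7 CPM against 122.5 ± 38.9). The mitochondrial kinase TK2 and the adaptor subunit AP5B1 were at 0.72 ± 0.18 and 0.99 ± 0.26. In the other direction RETN, a myeloid granule hormone (ENSG00000104918, chromosome 19, 7669044 to 7670454), was at -2.85 ± 0.66, and GATA2, a basophil and progenitor factor (ENSG00000179348, chromosome 3, 128479427 to 128493185), at -3.20 ± 0.74. The azurophil granule protein BPI, the transcript LINC02458 and LBH lay between -2.25 and -2.18. ALOX15 was at 0.68 ± 0.20 (559 ± 156 CPM against 348 ± 34.1), CLC at 0.11 ± 0.19, CCR3 at 0.29 ± 0.16, SIGLEC8 at 0.23 ± 0.17, IL5RA at -0.22 ± 0.17 and RNASE2 at -0.10 ± 0.66. FKBP5 was at -0.84 ± 0.35, TSC22D3 at -0.38 ± 0.28 and IL1RL1 at 0.27 ± 0.43. All of these had an edgeR adjusted p of 1.0.

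By list, 17 of 18 identity genes had a higher mean in moderate asthma (median 0.21, camera adjusted p = 3.1e-04; adjusted p = 0.104 with an estimated correlation), as did 11 of 13 eosinophil markers (median 0.22, adjusted p = 0.0236; adjusted p = 0.205 with an estimated correlation). Both lists hold markers that picked the cells. UMIs outside eosinophil-like cells made up 66.4 to 92.5% in healthy and 33.8 to 76.7% in moderate libraries. Whether RNA from other cells lowered these lists in health was not tested. Of 5 granule genes 4 were higher (median 0.52, adjusted p = 0.0284; adjusted p = 0.425 with an estimated correlation), and LGALS12 alone passed adjusted over the list alone. Of 24 interferon genes 20 were higher (median 0.27, adjusted p = 4.3e-04; adjusted p = 0.590 with an estimated correlation), none adjusted over the list alone. The interferon median was 0.11 without moderate replicate 4 and 0.49 without healthy replicate 2, and the call was lost without healthy replicate 1 (0.17, adjusted p = 0.104) or healthy replicate 3 (0.18, adjusted p = 0.0703); over all settings it was called in 25 of 29, with adjusted p from 8.3e-11 to 0.760. PLAUR passed among NF-kB genes adjusted over the list alone (adjusted p = 0.0106), and so did ALOX15 (adjusted p = 0.0406) and the prostaglandin receptor PTGER2 (-1.11 ± 0.29, adjusted p = 0.0377) among eicosanoid genes, whose mixed fry test gave adjusted p = 3.7e-04. Ribosomal protein genes were lower for 67 of 78 (median -0.18, adjusted p = 1.0e-05; adjusted p = 0.666 with an estimated correlation), which rested on healthy replicate 4: without it the median was 0.0025. The ribosomal call was also lost without moderate replicate 2 (-0.11, adjusted p = 0.0791), and the median was -0.28 without moderate replicate 5 and -0.30 without healthy replicate 3. Markers of other cells were lower too. All 7 basophil or mast markers (median -2.18, adjusted p = 1.6e-12; adjusted p = 0.0891 with an estimated correlation), all 4 progenitor markers (-1.07; adjusted p = 0.109 with an estimated correlation), all 6 conventional dendritic markers (-0.70; adjusted p = 0.425 with an estimated correlation) and all 4 cycling markers (-0.86; adjusted p = 0.205 with an estimated correlation) lay below health. Adjusted over the list alone, 5 basophil markers passed, among them MS4A3, ENPP3 and the histamine enzyme HDC, 2 progenitor markers and 2 cycling markers. Within 7.0.1 headers the medians were 0.55 for interferon, -0.14 for ribosomal protein, -2.50 for basophil and -1.29 for progenitor genes. The basophil median was -1.36 without healthy replicate 4. Healthy replicates 2 and 4 held 11.4% and 3.92% basophil-like cells, a limit on reading these genes as eosinophil expression. Their basophil list medians were 0.99 and 0.71. Healthy replicates 1 and 3 held 0.118% and 0.0798% basophil-like cells, below the moderate mean. Their list medians, -0.44 and -1.10, lay within the range of moderate libraries (-2.18 to -0.41).

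Severe asthma was compared with health to ask what marks circulating eosinophils in the disease that resists treatment. As lists, and with the preset correlation only, interferon-response genes stood higher and ribosomal protein genes lower in severe asthma. The eosinophil identity list was not called (median 0.04, adjusted p = 0.757). By edgeR 0 of 11381 genes passed (n = 3 against 4), with a lowest adjusted p of 0.2 and 1571 genes at unadjusted p under 0.05. DESeq2 called 123 genes, 45 higher and 78 lower, and limma-voom 0. Library values did not overlap for 1208 genes, where chance would give 5.71% of genes. The antiviral ubiquitin ligase RNF213 (ENSG00000173821, chromosome 17, 80260866 to 80398786) was at 1.15 ± 0.19 log2 (332.9 ± 62.5 CPM against 149.6 ± 29.5). MX2 (ENSG00000183486, chromosome 21, 41361943 to 41409390), an interferon-induced antiviral GTPase, was at 1.26 ± 0.25 (134.1 ± 64.4 CPM against 56.5 ± 10.5). The ubiquitin ligase subunit FBXW8 (ENSG00000174989, chromosome 12, 116910956 to 117031148) was at 1.21 ± 0.23, TSPOAP1 at 1.72 ± 0.32 and the DNA damage gene RAD9A at 1.07 ± 0.21. The ribosomal protein gene RPL9 (ENSG00000163682, chromosome 4, 39452521 to 39458949) was at -1.14 ± 0.23 (217.6 ± 19.9 CPM against 479.8 ± 88.4), with RPS13 at -1.34 ± 0.27 and the translation-associated NACA at -1.15 ± 0.23. IRF8 (ENSG00000140968, chromosome 16, 85898803 to 85922609), a factor of monocyte and dendritic lineages, was at -3.57 ± 0.72 (1.23 CPM against 18.4), and PNMA6A at -3.88 ± 0.72. Each of these had an adjusted p of 0.2. CLC was at -0.21 ± 0.22, CCR3 at -0.09 ± 0.19, SIGLEC8 at -0.27 ± 0.20, ALOX15 at 0.32 ± 0.23, RNASE2 at 0.85 ± 0.78, IL1RL1 at 0.50 ± 0.49, FKBP5 at -0.32 ± 0.42, TSC22D3 at -0.38 ± 0.34 and IL5RA at 0.00 ± 0.20.

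By list, 23 of 24 interferon genes were higher in severe asthma (median 1.28, camera adjusted p = 6.7e-15; adjusted p = 0.205 with an estimated correlation). Adjusted over the list alone 11 passed, among them ISG15 (2.10 ± 0.45, 201.7 ± 105 CPM against 47.2 ± 23.7), HERC5 (2.02 ± 0.48) and MX1 (2.33 ± 0.63). The median dropped to 0.75 without severe replicate 2. All 78 ribosomal protein genes were lower (median -0.86, adjusted p = 5.0e-49; adjusted p = 0.205 with an estimated correlation), 70 of them adjusted over the list alone. Library medians of each of these lists did not overlap between severe and healthy libraries, which chance gives for 5.71% of measures. Among NF-kB genes the cytokine IL1B was at -2.43 ± 0.60 and passed adjusted over the list alone (adjusted p = 0.0227), as did the nuclear RNA NEAT1 (0.90 ± 0.23, adjusted p = 0.00843) and the chaperone HSP90AB1 (-0.97 ± 0.23, adjusted p = 0.00887) in their lists. Heat shock genes were lower for 11 of 12 (median -0.22, adjusted p = 0.0297; adjusted p = 0.665 with an estimated correlation). Markers of other cells were lower as well. They were the 7 basophil or mast markers (median -3.61, adjusted p = 3.1e-09; adjusted p = 0.146 with an estimated correlation), the 4 progenitor markers (-2.51, adjusted p = 5.3e-07; adjusted p = 0.146 with an estimated correlation), the 6 conventional dendritic markers (-2.74; adjusted p = 0.205 with an estimated correlation), 8 of 10 classical monocyte markers (-1.46; adjusted p = 0.205 with an estimated correlation) and the 3 tested T cell markers (-2.15; adjusted p = 0.205 with an estimated correlation). All 7 basophil markers and all 4 progenitor markers passed adjusted over the list alone. Erythroid markers pointed the other way for 3 of 4 (median 2.37, adjusted p = 0.342, not called), with HBA1 at 2.79 ± 1.7 and HBB at 2.41 ± 1.6 (193.2 ± 181 CPM against 39.02 ± 67.6). Type 2 cytokine receptors had a median of 0.18 and a mean of -0.11, chemoattractant receptors 0.05 and -0.03, and secreted factors a median of -0.06 with a test pointing up; plasma cell markers had a median of 0.09 with a test pointing down, and none of these was called. Within 7.0.1 headers, where severe asthma had 1 library, the medians were 0.70 for interferon, -0.97 for ribosomal protein, -2.86 for basophil and -1.77 for progenitor genes. With only 3 severe libraries, 1 of them with a 7.0.1 header, group and header version could be separated only in part.

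Severe and moderate asthma were set side by side to test directly what differs between the grades of disease. As lists, and with the preset correlation only, the interferon genes were higher and the ribosomal protein genes lower in severe asthma here too. The interferon call was lost within 7.0.1 headers. In the edgeR fit of all 13 libraries no single gene passed. By edgeR 0 of 11381 genes passed (n = 3 against 6), with a lowest adjusted p of 0.278 and 1114 genes at unadjusted p under 0.05. DESeq2 called 43, of which 13 were higher and 30 lower, and limma-voom 0. Library values did not overlap for 421 genes (chance share 2.38%). FBXW8 was at 1.12 ± 0.20, RNF213 at 0.85 ± 0.17, RAD9A at 0.91 ± 0.18, the RNA cap methyltransferase CMTR1 at 0.87 ± 0.19 and the autophagy gene DRAM1 at 1.0 ± 0.22. The channel protein CLIC2 (ENSG00000155962, chromosome X, 155276211 to 155334657) was at -2.20 ± 0.40, RPL9 at -1.11 ± 0.22, BRI3 at -1.0 ± 0.20, IRF8 at -3.36 ± 0.68 and RAE1 at -0.88 ± 0.19. CCR3 was at -0.38 ± 0.17, SIGLEC8 at -0.49 ± 0.19, ALOX15 at -0.37 ± 0.22, CLC at -0.32 ± 0.21, IL5RA at 0.22 ± 0.18, RNASE2 at 0.96 ± 0.70, IL1RL1 at 0.23 ± 0.44, FKBP5 at 0.52 ± 0.38 and TSC22D3 within 0.31 (SE) of 0. By list, 23 of 24 interferon genes were higher (median 0.97, camera adjusted p = 4.9e-12; adjusted p = 0.449 with an estimated correlation) and 11 passed adjusted over the list alone, led by IFI44 at 2.50 ± 0.62. All 78 ribosomal protein genes were lower (median -0.71, adjusted p = 3.0e-45; adjusted p = 0.449 with an estimated correlation), 58 of them adjusted over the list alone. Of 13 mitochondrially encoded genes 12 were lower (median -0.45, adjusted p = 0.0040; adjusted p = 0.565 with an estimated correlation). Markers of basophils (median -1.83), conventional dendritic cells (-1.90), monocytes (-1.14) and progenitors (-1.32) were lower, with adjusted p of 0.0031 to 0.0068, and none was called with an estimated correlation. The globin genes HBA1, HBA2 and HBB, carried by red cells, stood at 4.15, 4.15 and 3.72. The interferon median was 0.29 within 7.0.1 headers (adjusted p = 0.395, 1 severe library) and 1.77 within 6.0.0 (2 severe and 2 moderate libraries), and 0.48 without severe replicate 2. The ribosomal median was -0.81 and -0.71 within these versions.

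The mean of the moderate and severe effects was tested to find what asthma of either grade shares against health. As lists, interferon genes were higher and ribosomal protein, basophil and progenitor genes lower with the preset correlation, and no single gene passed. By edgeR 0 of 11381 genes passed (n = 9 against 4), with a lowest adjusted p of 0.366 and 1081 genes at unadjusted p under 0.05. DESeq2 called 20 genes, 13 higher and 7 lower, and limma-voom 0. Library values did not overlap for 64 genes (chance share 0.280%). RNF213 was at 0.73 ± 0.16, the antiviral signalling gene TRIM14 (ENSG00000106785, chromosome 9, 98069275 to 98119212) at 1.22 ± 0.27, AP5B1 at 1.11 ± 0.25, TSPOAP1 at 1.24 ± 0.28 and MX2 at 0.91 ± 0.21. GATA2 was at -4.50 ± 0.78, PNMA6A at -2.63 ± 0.49, LBH (ENSG00000213626, chromosome 2, 30231369 to 30323730) at -2.67 ± 0.51, the progenitor protease PRSS57 at -1.96 ± 0.42 and HDC at -3.09 ± 0.69. ALOX15 was at 0.50 ± 0.19, RNASE2 at 0.37 ± 0.64 and IL1RL1 at 0.38 ± 0.41, while CLC, CCR3, SIGLEC8 and IL5RA lay between -0.11 and 0.10. FKBP5 was at -0.58 ± 0.33 and TSC22D3 at -0.38 ± 0.27. By list, 22 of 24 interferon genes (median 0.87, camera adjusted p = 1.3e-11; adjusted p = 0.267 with an estimated correlation) were higher, 2 adjusted over the list alone, and the median dropped to 0.48 without severe replicate 2. All 78 ribosomal protein genes (median -0.50, adjusted p = 1.8e-36; adjusted p = 0.262 with an estimated correlation) were lower, 39 adjusted over the list alone, with a median of -0.32 without healthy replicate 4. The 7 basophil or mast markers (median -2.70, adjusted p = 9.0e-15; adjusted p = 0.0512 with an estimated correlation) and the 4 progenitor markers (-1.85, adjusted p = 5.8e-09; adjusted p = 0.0512 with an estimated correlation) were lower, each gene also adjusted over the list alone, with directional fry adjusted p of 0.0318 and 0.0307. Conventional dendritic (-1.64), T cell (-1.42), monocyte (-0.89) and cycling (-0.86) markers were called lower with the preset correlation only. Within 7.0.1 headers the medians were 0.60 for interferon, -0.57 for ribosomal protein, -2.81 for basophil and -1.47 for progenitor genes.

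**Figure D3:**
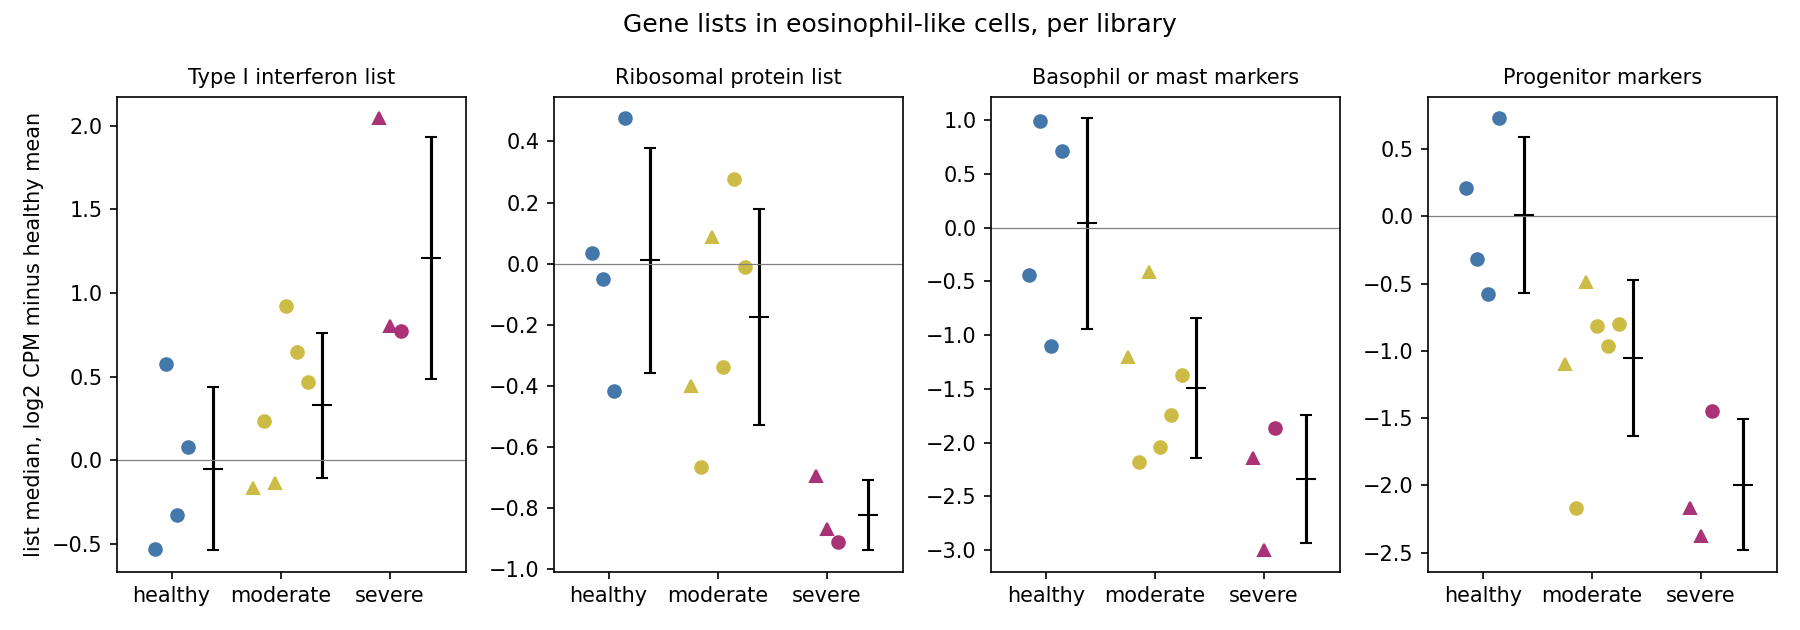
Median over list members of the log2 level (vertical axis, relative to the mean of healthy libraries) for interferon, ribosomal protein, basophil or mast and progenitor genes in each of the 13 eosinophil libraries, with mean and SD beside each group. Circles are libraries with a 7.0.1 header and triangles those with 6.0.0; severe medians for interferon genes run from 0.77 to 2.05 and healthy ones from -0.53 to 0.58.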

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

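The tests of a single severe library, of the header version and of correlations within groups were written after the results they measure had been seen. So were the split tests of severe against healthy libraries for gene counts and for the interferon and ribosomal lists. The tests in other cells and the remaining splits with a written prediction were written before. No prediction was written for the splits of the interferon and ribosomal lists in moderate or all asthma. The same holds for the progenitor list in moderate asthma and for the basophil and progenitor lists in severe asthma against either group.

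Of 106 groups of 4 or more libraries tested for a value far from the others, over 37 genes and the list, share and depth measures, 10 held one, and chance alone gives about 1 in 20. Severe replicate 1 was far from the other severe libraries in 4 classes. It had 2.27% eosinophil-like cells where the nearest severe library had 86.2%, and it had 6.45% basophil-like or mast-like cells (next 0.455%), 18.4% erythroid-like cells (next 1.96%) and 71.4% cells in unnamed clusters (next 9.10%). These shares are parts of one whole, so they are not 4 separate findings. Moderate replicate 3 stood apart in the same way, with 9472 kept cells (next 4238), 33.9% eosinophil-like cells (next 79.0%) and 65.0% in unnamed clusters (next 20.03%), mostly a cluster that took 82.9% of its cells from this library and was led by immunoglobulin and noncoding transcripts. The floor of 200 UMIs removed no barcode of moderate replicate 3, whose lowest held 266, so background among its kept cells was not excluded. Healthy replicate 4 had 5.26% plasma-like cells (next 0.889%). Moderate replicate 2 had the lowest progenitor list median among moderate libraries, -2.16 (next -1.10). Healthy replicate 1 had 23.5 CPM of IL1RL1, the IL-33 receptor (next 52.9).

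A second kind of result was a list whose effect over health differed between severe and moderate asthma, tested as the severe minus moderate coefficient with camera. These were type I interferon genes (0.97, adjusted p = 4.9e-12), cytosolic ribosomal protein genes (-0.71, adjusted p = 3.0e-45), mitochondrially encoded genes (-0.45, adjusted p = 0.0040), heat shock genes (-0.20, adjusted p = 0.0240) and markers of conventional dendritic cells (-1.90, adjusted p = 0.0031), progenitors (-1.32, adjusted p = 0.0061), classical monocytes (-1.14, adjusted p = 0.0061) and basophils or mast cells (-1.83, adjusted p = 0.0068). With an estimated correlation none was called, with adjusted p from 0.449 to 0.565.

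The first pattern weighed was the higher interferon list in severe asthma (median 1.28 over health). List p-values in this part use the preset correlation; with an estimated one this list and the ribosomal list lost their calls in severe asthma (adjusted p = 0.205 for each), as did the basophil and progenitor lists in all asthma (adjusted p = 0.0512 for each). A single severe library may explain part of the pattern, and the median of 0.75 without severe replicate 2 (adjusted p = 1.4e-06) counts against it as the whole cause. The fit with version as a covariate counts against the header version as the whole cause, since the median there was 1.26 (adjusted p = 1.5e-13). Within 7.0.1 headers, with 1 severe library, it dropped to 0.70 (adjusted p = 6.1e-04), and for severe against moderate asthma it was 0.29 there (adjusted p = 0.395) but 1.77 within 6.0.0, so a part of the pattern may still go with the version or with severe replicate 2, which carries 6.0.0. RNA from other cells of the library was left open: the same list was 0.92 higher in the other kept cells, with 23 of 24 genes higher, and the median difference between eosinophil-like and other cells was 0.11, larger in eosinophil-like cells for 16 of 24 genes. The list median and the percent of UMIs outside the class correlated at r = -0.530 pooled (permutation p = 0.0606) and -0.267 within groups (permutation p = 0.458), a sign that goes against this source, but neither passed. A response to interferon in all cells of the blood sample, the biological reading, would look the same, so these libraries cannot separate these readings. Chance was not excluded, as 4 of 35 splits gave a list p as small (real 15.4 on the -log10 scale, highest other 24.4), nor was it for this list in moderate asthma (35 of 100) or in all asthma (12 of 100).

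The second pattern was the lower ribosomal protein list in severe asthma (median -0.86 over health). Version as a covariate left it at -0.93 (adjusted p = 5.6e-36), which counts against the header version. It was not a property of whole libraries in an obvious way, since the list was at -0.0471 in the other kept cells with 26 of 78 genes higher, yet that test could not settle the matter because those cells are of other types. RNA from other cells could lift ribosomal genes in libraries with few eosinophils: the list median and the percent of UMIs outside the class correlated at r = 0.494 within groups (permutation p = 0.0898, adjusted p = 0.210), 0.630 pooled (permutation p = 0.0219; rho 0.527, permutation p = 0.0663) and 0.529 without the 2 farthest libraries, which leaves it open. Chance was not excluded against health (2 of 35 splits, real 49.8, highest other 77.9). For severe against moderate asthma few splits gave a list p as small (2 of 84, the real one included, real 46.0, highest other 63.2). That count is not adjusted over the list splits, so chance was not excluded there either. It was not excluded in moderate asthma (48 of 100) or in all asthma (6 of 100).

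The third pattern was the lower basophil and progenitor markers in asthma (medians -2.70 and -1.85). For progenitor markers the relation that RNA from other cells needs was present, though not past the threshold once adjusted, so this source is possible rather than shown: the list median followed the percent of UMIs outside the eosinophil-like class at r = 0.767 within groups (permutation p = 0.00986, adjusted p = 0.0592 over 6 relations; rho 0.714, permutation p = 0.0134), 0.841 pooled and 0.746 without the 2 farthest libraries. For basophil markers it was left open, with r = 0.614 within groups against the basophil-like share (permutation p = 0.105; rho 0.593, permutation p = 0.0822), 0.719 pooled, and 0.136 without the 2 farthest libraries, so that relation rests on those. Few splits gave a p as small for the basophil list in moderate asthma (3 of 100 splits, real 13.3, highest other 25.04). The same held for that list in all asthma (3 of 100, real 15.3, highest other 23.7). It also held for the progenitor list in all asthma (2 of 100, real 9.15, highest other 11.5). These counts include the real split and are not adjusted over the list splits, so they do not exclude chance. Erythroid markers did not follow the lower markers of other cells (median 0.40 in all asthma, not called). In moderate asthma chance was not excluded for the progenitor list (6 of 100), nor in severe asthma against health for the basophil list (2 of 35). In severe against moderate asthma it was not excluded for either list (16 of 84 for basophil and 8 of 84 for progenitor markers). For the progenitor list in severe asthma against health only the real split gave a p as small (1 of 35). That is the smallest count possible and is likewise unadjusted. In all asthma the difference was larger in eosinophil-like cells than in the other kept cells, where the medians were -0.83 for basophil markers (all 7 smaller there) and -0.46 for progenitor markers (all 4), and in moderate asthma the progenitor median there was -0.15. A difference in eosinophil expression would give this, but so could fewer foreign transcripts per eosinophil, so it does not separate the readings.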

How the results depend on the processing

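Settings that use the Cell Ranger version of the header, keep severe replicate 1, drop the cluster of fewest UMIs or leave out ribosomal genes were chosen after seeing the data; the rest were fixed before. Over all settings, 138 gene counts stayed within 1.5 times the reported count and 17 grew. For the interferon, ribosomal protein, basophil and progenitor lists, the only ones followed through every setting, 527 values kept direction and side of the threshold, 47 lost their call, 20 gained one, 5 moved and 2 reversed. For named genes these were 3169 kept, 6 lost, 37 gained, 79 moved and 2 reversed.

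The comparisons of healthy eosinophil-like cells with mononuclear and monocyte-like cells kept their counts within 1.5 times under every tool, filter and floor: 5339 to 11012 and 4917 to 7626 genes. Leaving out each library in turn gave 6896 to 10140 and 5041 to 6188. The highest came without healthy eosinophil replicate 4, when more genes were tested. With all barcodes summed, both comparisons share one input and gave 5339 genes. A similar count did not mean the same genes. Only 2516 of these were among the 7650 reported against mononuclear cells, and 2034 among the 6043 against monocyte-like cells. TSC22D3 reversed to -0.0814 (adjusted p = 0.920) in each.

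For moderate asthma against health every setting gave 0 genes. Severe asthma against health gave 0 with edgeR but 123 with DESeq2, 36 without the gene filter, 1 with only the groups compared and 104 with 7.0.1 headers only, where the lone severe library is assumed to vary like the other groups. Severe against moderate asthma gave 43 with DESeq2, 12 without the filter, 333 with 7.0.1 headers only and 1 with 6.0.0 headers only. All asthma gave 20 with DESeq2, 10 without the filter and 8 with 7.0.1 headers only. RLE factors, limma-voom, the UMI floors, the mitochondrial limit, doublets kept, all barcodes summed and version as a covariate gave 0 in all 4. Leaving out each library in turn gave 0 to 1 genes for severe asthma and 0 to 4 for severe against moderate asthma, the highest of each without severe replicate 3, and 0 to 2 for all asthma, the highest without healthy replicate 1 or healthy replicate 3. The cause was not tested. In the simulated counts DESeq2 also made more false calls than edgeR (22 against 5 for severe asthma against health).

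Genes of settings that called 5 or fewer are named after their values were seen. THBS1 passed for severe asthma with only the groups compared (-3.13, adjusted p = 0.0275; 0.224 in the reported fit) and for severe against moderate asthma with 6.0.0 headers only (-5.41, adjusted p = 0.0326). Without severe replicate 3, SIPA1L1 passed for severe asthma (1.88, adjusted p = 0.00483) and, for severe against moderate asthma, IFI44L (3.30), KCNA7 (3.45), SIPA1L1 (1.39) and BCL2A1 (-1.37) at adjusted p = 0.0194. In all asthma AKAP12 (-3.60) and PNMA6A (-2.95) passed without healthy replicate 1 (adjusted p = 0.0344), and GATA2 (-4.93, adjusted p = 0.0164) and ENPP3 (-3.57, adjusted p = 0.0216) without healthy replicate 3.

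With the title number as a replicate block, 1 gene passed for severe asthma against health (HBA1, 8.05, adjusted p = 0.00529) and 2 for severe against moderate asthma (HBA1, 8.03, and HBA2, 8.19, adjusted p = 0.00171 and 0.0193), and 0 in the other asthma comparisons. For the healthy comparisons a replicate block of the title code gave 9203 genes, against 9755 in the same 6 libraries without the block, and 5893 against 5947 for monocyte-like cells. It changed no other call. Deviations from group means within these pairs correlated at 0.0863 to 0.122 and 0.0563 to 0.163, each library best with its own number in 3 of 3 cases, a hint from the data only. Between eosinophil groups the numbers gave -0.269 to 0.152.

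Over all lists, 4 of 57 calls held with an estimated correlation. These were the identity and eosinophil marker lists of the healthy comparisons. Both lists hold genes that picked the cells, so no call free of that choice held. The interferon list in severe asthma was called in 27 of 29 settings (median 0.70 to 1.56, adjusted p 8.9e-22 to 0.205) and the ribosomal list in 26 of 28 (-0.99 to -0.51, 2.6e-69 to 0.205). Apart from the estimated correlation and directional fry, every setting of a list used camera with the preset correlation. The settings thus share that assumption, and their number does not test it. With camera at the estimated correlation both lists lost the call (adjusted p = 0.205 for each). The ribosomal list in moderate asthma reversed to 0.0025 without healthy replicate 4 (adjusted p = 0.874; over all settings -0.30 to 0.0025, 5.2e-17 to 0.874). The basophil list in moderate asthma was -1.36 without healthy replicate 4. In severe against moderate asthma the basophil list reversed to 2.18 at the floor of 100 UMIs (adjusted p = 0.249; over all settings 6.7e-11 to 0.751) and lost its call without moderate replicate 3 (-1.17) or severe replicate 3 (-1.02); it was -1.17 without moderate replicate 1. The progenitor list there lost its call without severe replicate 2 or severe replicate 3 (adjusted p = 0.0950 and 0.0507). In severe asthma against health the floor of 100 UMIs took the basophil list to -0.79 (adjusted p = 0.483; over all settings 2.2e-15 to 0.483). At this floor a cluster of 17267 cells of few UMIs took the basophil name, the share of basophil-like cells was -19.5 points in severe minus moderate asthma (exact permutation p = 0.0286), and 2 share tests had an unadjusted exact p under 0.05, where 0 had in the reported setting. Leaving out each library gave 0 to 1 such share tests (1 without healthy replicate 4) and 0 to 1 depth tests (1 without moderate replicate 1).

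Depth limits genes of few counts: PNMA6A had 9 counts over the 3 severe libraries and CLIC2 9, so their folds are loose.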

Other observations

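Of the tests given here, the split test of severe against healthy libraries was written after its result had been seen, and the others before.

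Single genes of survival and of glucose and oxygen use differed between healthy eosinophil-like and mononuclear cells, although neither list was called by camera. The survival genes BCL2A1 and MCL1 rose by 3.71 ± 0.18 and 2.05 ± 0.15 on the log2 scale against all mononuclear cells, while BCL2, the survival factor of lymphocytes, was at -4.62 ± 0.52. The death-promoting PMAIP1 (3.09 ± 0.26) rose beside them. Hexokinase HK2 (3.53 ± 0.18) and the hypoxia factor HIF1A (3.16 ± 0.24) rose, whereas the late glycolytic PKM was at -1.75 ± 0.19. Against monocyte-like cells BCL2A1 (2.82 ± 0.17) and HK2 (2.10 ± 0.21) also rose. All of these passed the edgeR threshold. The apoptosis list as a whole had 9 rises and 5 falls of 19 and a median of 0.30 (adjusted p = 0.107), and the glycolysis and hypoxia list 4 rises and 8 falls of 19 and a median of 0.04 (adjusted p = 0.913).

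Single growth factor and chemokine transcripts differed as well, from lists that were not called. CSF1 (5.71 ± 0.33), the chemokine CCL23 (8.49 ± 0.60) and the epithelial growth factor TGFA (4.6 ± 0.42) rose against mononuclear cells, and CCL5, a chemokine of T and NK cells, was at -7.30 ± 0.47. The tryptophan enzyme IDO1 rose by 5.35 ± 0.52 and by 6.70 ± 0.32 against monocyte-like cells. In the same interferon gamma list GBP5 (-6.60 ± 0.59) and GBP1 (-4.77 ± 0.57) fell. The adenosine receptor ADORA3 (7.63 ± 0.30) and the kinase SGK1 (4.90 ± 0.34), both in the glucocorticoid list, rose. Of 5 transcripts retained in the nucleus 3 fell, NEAT1 (-2.03 ± 0.17), MALAT1 (-2.17 ± 0.26) and KCNQ1OT1 (-1.95 ± 0.29), named after their values were seen, and the list was not called by camera (adjusted p = 0.107).

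In the kept cells outside the eosinophil-like class, edgeR called 0 of 15520 genes for moderate asthma against health and 0 for severe against moderate asthma, with 707 and 2186 at unadjusted p under 0.05. These cells are of several types in shares that differ by library.

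Gene counts under other splits of the same libraries gave a further test. Where the real count was 0, every split matched it: 100 of 100 splits for moderate asthma against health, 35 of 35 for severe asthma against health, 84 of 84 for severe against moderate asthma and 100 of 100 for all asthma. That outcome was fixed, so these counts say nothing about chance. The highest other counts were 11, 2, 100 and 267 in the same order. The split with 267 set moderate replicate 1, severe replicate 5, healthy replicate 2 and healthy replicate 3 against the rest and was the highest of 100. For eosinophil-like against mononuclear cells only the real split gave as many genes (1 of 35, real 7650, highest other 57). The same held against monocyte-like cells (1 of 35, real 6043, highest other 0). Eosinophil-like and monocyte-like cells were picked by their transcripts, and every other split mixes cell types and preparations. These 2 outcomes were therefore expected from the choice of cells and are no test of chance. For the interferon list in severe against moderate asthma chance was not excluded (12 of 84 splits, real 12.5 on the -log10 scale, highest other 28.1).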
